A study of Homo sapiens with 2 samples.

How the data were processed

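The series compared SWAN-71 cells, a telomerase-immortalized line of human first-trimester trophoblast, with and without epidermal growth factor (EGF), the ligand of the receptor tyrosine kinase EGFR. Per the labels' protocols, cells were starved in serum-free medium for 4 h, after which one culture received EGF at 10 ng/ml for 24 h while the control stayed in serum-free medium for 24 h. Each group held 1 library, so 2 libraries were compared and no spread between cultures could be estimated. Per the labels' protocols, libraries came from total RNA with the TruSeq Small RNA kit, which ligates adapters to both RNA ends and amplifies by PCR without molecular identifiers. Ligation efficiency depends on the sequence of each miRNA, so levels of different miRNAs within a library compare less well than levels of 1 miRNA between libraries.

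Per the series' design text, the authors sequenced on an Illumina Genome Analyzer IIx, trimmed adapters and low-quality bases in CLC Genomics Workbench 6.5.1 and mapped the trimmed reads to miRBase release 21. Mismatch settings, length limits and the treatment of reads that match several miRNAs are not given in the sources used here. The authors deposited 2 tables, one of all miRNAs called common to both libraries and one of those called differential, with the same columns. Per the file headers, each row holds the read counts of a mature miRNA in each library, its normalized values, a fold change and a P-value. The deposited read counts were whole numbers and had not been normalized. A second header line at the end of the table of all miRNAs names the count columns Mature 5', although rows for 3p arms hold counts too. Whether the counts are of exact mature matches or also of variants is not given in the sources used here. The deposited normalized values were scaled to mature miRNA reads (RPM), since the ratio of count to value was constant within each library. The deposited signed fold, handled as a score with no fixed range, lay within 1% of the ratio of the normalized values for 872 of 872 miRNAs with counts. It was written as a negative number where the untreated library was higher. The deposited p-value came from 1 library against 1, and the test behind it is not given in the sources used here, so it was used only to describe how the authors chose their list. The column headers name the libraries by code alone, and the name of the deposited comparison pairs these codes with control and EGF. Every direction reported here rests on that pairing.

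The tables held 889 miRNAs, of which 17 stood at 0 in both libraries and 872 had counts in both. None stood at 0 in 1 library only, as the word "common" in the table's title implies, so a miRNA switched fully on or off could not be seen. Counts summed to 2614529 in the untreated library and 1053932 in the EGF library, a depth ratio of 2.48. From the scale of the deposited per-million values, about 643 reads of the untreated library (0.0246%) and 83 of the EGF library (0.00787%) lay outside the rows analysed here. A single read was worth 0.382 CPM (the unit of counts scaled to the library total) in the untreated library and 0.949 CPM in the EGF library.

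Counts were divided by the table total of their library to give CPM. The log2 ratio of EGF over untreated was taken after adding 0.545 CPM to both values, which is worth 1 read at the mean library size, so it understates changes of rare miRNAs. Folds in the text are on that scale unless stated otherwise. The counting interval of each ratio is the exact (Clopper-Pearson) 95% interval of the EGF share of a miRNA's counts, given both totals and without the added value. With 1 library per group no test of the conditions was possible, and no p-value was computed. A fixed size rule was used in place of a test: at least 2-fold, an interval that excludes equal levels, and at least 20 counts over both libraries. Words such as higher and lower, without the size rule named, describe values or intervals in these 2 libraries. All intervals cover counting error only, since 1 library per group gives no spread between cultures, and they treat reads as independent. PCR reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error.

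The size rule, the 26 miRNA lists, the rule for named miRNAs and all alternatives but one were set before the data were examined. The text names up to 10 largest rises and 10 largest falls past the size rule with at least 100 counts, the 5 most abundant miRNAs, and for each list its most abundant member and the member with the largest log2 ratio in size among those with at least 20 counts. It also names miR-21, miR-221, miR-222, miR-210, miR-7 and miR-92a-1-5p whatever their values. These rules picked 59 miRNAs, and others named were chosen after their values were seen. List members were matched on the number and letter of the miRNA name, with any arm. The lists held placental and stem cell clusters, growth-factor and ERBB-linked miRNAs, broad families, markers of other cell types, and miRBase entries that overlap other RNAs. For each of the 18 lists with at least 3 members at 20 or more counts, the median log2 ratio was set against 10000 random lists of the same size, each member drawn from the 20 miRNAs nearest in mean CPM. The percentile describes these 2 libraries and is not a p-value.

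The size rule and the intervals were tested on simulated data drawn from the real means and library sizes of the 872 miRNAs with counts in both libraries. With no change, a median of 1 miRNA was called higher and 2 lower by the size rule, and at most 5 and 6 in 100 simulated pairs. Beside 200 changed miRNAs, a mean of 5.1 unchanged miRNAs per run passed the rule at 2.5-fold changes and 8.4 at 4-fold changes. Those 200 were drawn at random at any level, while 22 miRNAs passed the rule in the real libraries. These means are therefore no estimate of false calls among the 22. Of miRNAs changed 2.5-fold, 59.5% with at least 20 but under 100 counts and 90.6% with 100 or more were recovered, and of those changed 4-fold, 87.3% and 100%. miRNAs below 20 counts cannot pass the rule and were left out of these shares. The list step was tested apart from these libraries, on made-up levels, independent normal ratios and lists of equal size. Among such simulated lists with no effect, 7.5% fell outside the central 95% of their random lists. Detection limits were computed from CPM without the added value, so for rare miRNAs they exceed the same changes on the scale of the reported folds. At 20 counts over both libraries the smallest rise whose interval excludes equal levels was 3.03-fold, at 100 counts 1.59-fold, at 1000 counts 1.15-fold and at 10000 counts 1.04-fold. The smallest such falls were 7.66-fold, 1.72-fold, 1.16-fold and 1.05-fold, so falls of rare miRNAs were harder to detect than rises.

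Alternatives covered scaling by edgeR 4.0.16 TMM factors, by DESeq2 1.42.0 size factors, by totals without the 10 most abundant miRNAs and by the deposited per-million values. They also covered added values worth 0.5 or 5 reads, count minimums of 1 and 100, 1.5- and 4-fold thresholds, merged copies, unmatched random lists, shares without entries that overlap other RNAs, and the deposited list rebuilt from its stated thresholds. A thinning of the untreated library to the EGF total was added after seeing the data. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3. The tables name no genome build and give no coordinates, so hairpin positions were taken by name from GENCODE 29 on GRCh38, which matched 888 of 889 miRNAs. In 3 pairs of rows, miR-423-5p with miR-3184-3p, miR-199a-3p with miR-199b-3p and miR-103a-3p with miR-103b, counts in both libraries lay within 0.5% and the hairpins shared at least 18 nt. Such rows appear to hold the same reads and cannot be assigned to 1 hairpin.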

Results

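The study asked how EGF changes the miRNAs of trophoblast cells. Small RNA was sequenced from SWAN-71 cells kept for 24 h in serum-free medium without EGF (1 library, 2614529 miRNA counts) or with EGF at 10 ng/ml (1 library, 1053932 counts). Of 872 miRNAs with counts in both libraries, 505 had at least 20 counts over both and 330 had at least 100. The median count was 24.5 in the untreated library and 9 in the EGF library. No value has a replicate check, and each interval is the exact 95% counting interval.

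After 24 h of EGF, 14 miRNAs were at least 2-fold higher and 8 at least 2-fold lower past the size rule, while most miRNAs differed little. The largest rise was that of miR-4792, which stood at 93.3 CPM in the untreated library and 653.7 CPM with EGF, 6.97-fold higher (log2 ratio 2.80, interval 2.60 to 3.03). miR-34a-5p, a direct target of the tumour suppressor p53, stood at 73.8 CPM and 257 CPM, 3.47-fold higher (log2 1.79, interval 1.53 to 2.07). miR-210-5p, from the hairpin of the hypoxia-induced miR-210, was 2.37-fold higher (log2 1.25, interval 0.81 to 1.71). The falls with at least 100 counts were those of miR-30c-1-3p (log2 -1.27, interval -2.02 to -0.64) and miR-2682-5p (log2 -1.02, interval -1.64 to -0.47, and -0.97 with 5 reads added).

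Other rises with at least 100 counts were those of miR-4454 (201.6 and 1018 CPM, log2 2.33), miR-3960 (15.7 and 73.1 CPM, log2 2.18), miR-6087 (log2 1.40), miR-7704 (log2 1.34) and miR-1246 (log2 1.07). miR-4454, miR-6087 and miR-1246 belong to the fixed list of entries that overlap other RNAs, so their reads can come from other transcripts. The hairpins of miR-4792, miR-3960, miR-6087, miR-7704 and miR-210 had GC contents above 70%. Subtracting a trend on hairpin GC fitted over every miRNA with at least 100 counts left miR-4792 at a log2 ratio of 2.48, miR-3960 at 1.26 and miR-6087 at 1.00, with miR-7704 and miR-210-5p below 2-fold (0.97 and 0.94). All of these miRNAs are in that fit, so it can remove part of their own rise. A trend fitted without the miRNAs higher past the size rule left them, in the same order, at 2.78, 2.02, 1.36, 1.31 and 1.23. Below 100 counts, miR-5787, miR-4634, miR-4516, miR-9-3p, miR-539-5p and miR-33a-3p were higher past the size rule, with log2 ratios between 1.01 and 1.33. The trend over every miRNA with at least 100 counts, whose fit leaves out these 6, put 4 of them below 2-fold: miR-5787 (log2 0.61), miR-4634 (0.77), miR-4516 (0.95) and miR-539-5p (0.96). On the lower side stood miR-664a-3p (63 and 10 counts, also in the list of entries that overlap other RNAs), miR-3614-5p (50 and 8), miR-3135b (66 and 8), miR-4662a-5p (27 and 2), miR-3127-5p (24 and 1) and miR-4448 (49 and 1). The ratio of miR-4448 had an interval of -9.64 to -1.76 (log2), so its size is poorly known.

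**Figure D1:**
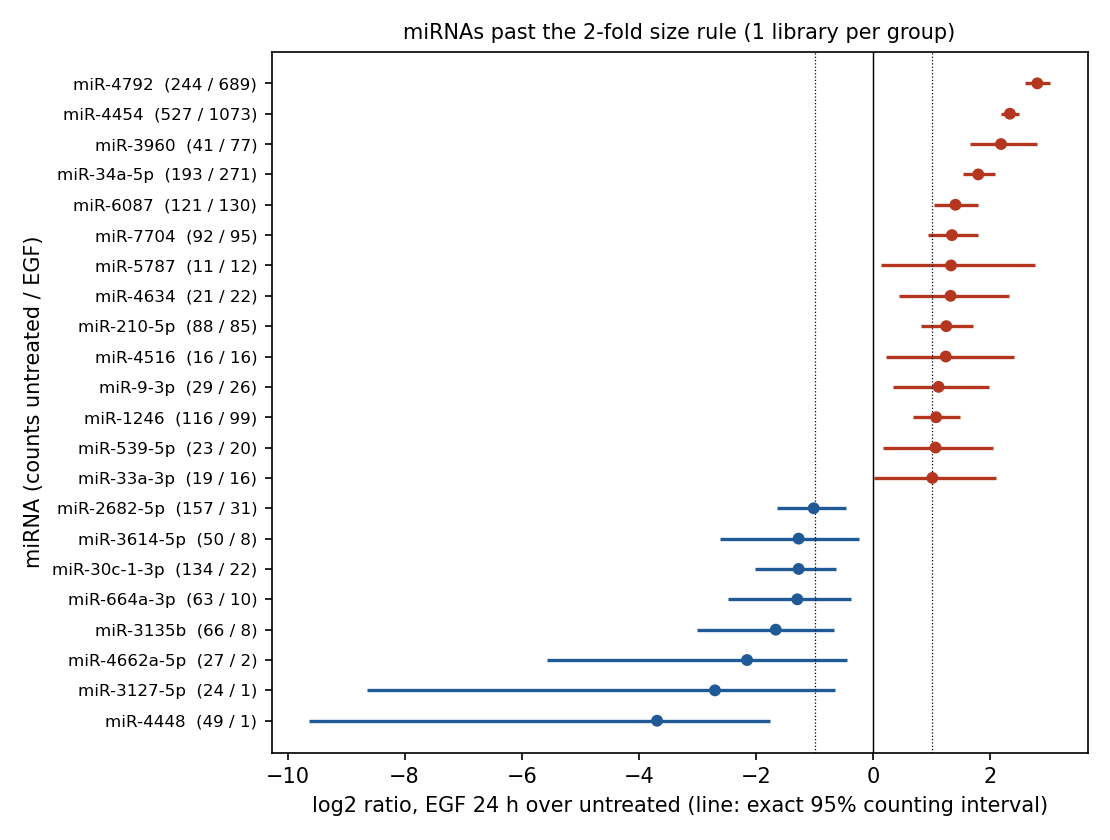
The 22 miRNAs past the size rule, with the log2 ratio of EGF over untreated on the horizontal axis (points) and its exact 95% counting interval (lines), 1 library per group, counts in the untreated and EGF libraries beside each name and dotted lines at 2-fold. miR-4792 and miR-4454 have narrow intervals above 2, while miR-4448, with 1 count in the EGF library, spans -9.64 to -1.76.

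In GENCODE 29 (GRCh38), the miR-4792 hairpin lies on chromosome 3 at 24521362 to 24521435 on the minus strand, in no annotated gene of that strand and opposite THRB-AS1. The miR-34a hairpin (chromosome 1, 9151668 to 9151777, minus strand) overlaps an exon of its host transcript MIR34AHG. The miR-3960 hairpin (chromosome 9, 127785833 to 127785923, plus strand) overlaps an exon of the kinase gene CDK9, and that of miR-7704 (chromosome 2, 176188843 to 176188901, plus strand) an exon of HOXD1. The miR-210 hairpin (chromosome 11, 568089 to 568198, minus strand) lies in an intron of MIR210HG. The hairpins of miR-4454 (chromosome 4, 163093574 to 163093628, minus strand), miR-6087 (chromosome X, 109054542 to 109054590, plus strand) and miR-1246 (chromosome 2, 176600980 to 176601052, minus strand) lie in no annotated gene of their strand. The miR-30c-1 hairpin (chromosome 1, 40757284 to 40757372, plus strand) lies in an intron of NFYC, and the miR-2682 hairpin (chromosome 1, 98045242 to 98045351, minus strand) overlaps an exon of MIR137HG.

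The rest of the profile was close between the libraries. Of the 330 miRNAs with at least 100 counts, 91.2% differed by less than 1.5-fold, and their median log2 ratio was -0.017. Across the 505 miRNAs, which are not independent replicates, log2 CPM correlated with Pearson r = 0.984 and CPM with Spearman rho = 0.978. Intervals excluded equal levels for 66 higher and 87 lower miRNAs, 30.3% of 505, where simulated pairs with no change and independent reads gave a median of 4.16%. These intervals compare the 2 libraries and not the conditions.

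**Figure D2:**
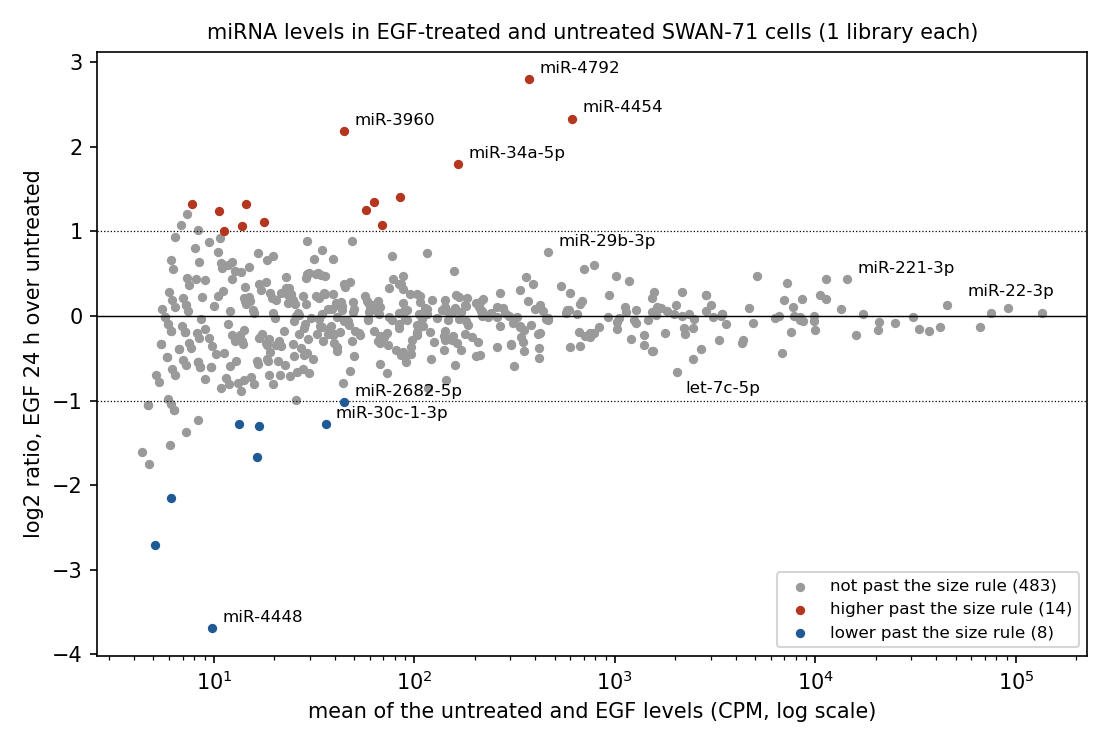
Each point is 1 of 505 miRNAs with at least 20 counts over both libraries, with its mean level in CPM on a log scale (horizontal) and its log2 ratio of EGF over untreated (vertical), 1 library per group. Dotted lines mark 2-fold; 14 miRNAs were higher (red) and 8 lower (blue) past the size rule, and no miRNA with a mean level above 1000 CPM was among them.

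miR-22-3p was the most abundant miRNA in both libraries. It took 13.4% of counts without EGF (interval 13.3% to 13.4%) and 13.8% with EGF (interval 13.7% to 13.8%). miR-21-5p, an oncogenic miRNA hosted by VMP1, took 8.86% and 9.48%, let-7a-5p 7.39% and 7.57%, miR-10b-5p 6.93% and 6.35%, and miR-10a-5p 4.35% and 4.76%. Together these 5, the most abundant by mean level, held 40.9% and 41.9% of counts.

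Of the growth-factor-inducible list (miR-21, miR-221, miR-222, miR-155, miR-132 and miR-212, whose host transcripts answer to ERK, AP-1 or CREB), no member passed the size rule. Of its 11 measured members, 4 had intervals above and 2 below equal levels, and the median of 0.098 lay at percentile 94.3 of matched random lists. miR-221-3p (log2 0.44, interval 0.41 to 0.47) and miR-21-3p (log2 0.44, interval 0.41 to 0.47) were both higher with EGF, and miR-222-3p (log2 0.19) and miR-21-5p (log2 0.10) by less. Their partner arms miR-222-5p (log2 -0.40, interval -0.70 to -0.11) and miR-221-5p (log2 -0.13, interval -0.31 to 0.05) did not share that direction. miR-212-3p had the largest ratio of the list (log2 0.53), with 27 and 16 counts and an interval that held equal levels. miR-155-5p, named after its value was seen, stood lower (7578 and 2140 counts, log2 -0.51, interval -0.58 to -0.44).

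The list of miRNAs known to repress EGFR, ERBB2 or ERBB3 had 13 measured arms, 7 of them partner arms (such as miR-125b-1-3p and miR-331-5p) that the matching by name brought in. Of the 13, 4 had intervals above equal levels and none below (miR-146a-5p, miR-146b-5p, miR-125b-5p and the partner arm miR-125b-1-3p). The median of 0.14 (counting interval -0.052 to 0.255) lay at percentile 96.3. miR-146a-5p was the most abundant (log2 0.25, interval 0.21 to 0.28), and miR-331-5p had the largest ratio in size (log2 -0.69, interval -1.57 to 0.07). miR-7-5p, which represses EGFR, had 40 and 11 counts (log2 -0.53, interval -1.66 to 0.44), and miR-7-1-3p a log2 ratio of -0.21 (interval -0.69 to 0.26). Differences within these intervals were not detectable at this depth. With a minimum of 100 counts, the list's 10 remaining members had a median of 0.18, at percentile 98.7, and with no count minimum the median was -0.01, at percentile 76.8.

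The miR-30 family stood lower with EGF as a group. Of its 11 members, 7 had intervals below equal levels and none above, and the median of -0.20 lay at percentile 1.74. miR-30a-5p, its most abundant member, had a log2 ratio of -0.17 (interval -0.19 to -0.14), and miR-30c-1-3p was the member past the size rule. Against unmatched random lists the percentile was 11.8. The let-7 family, which restrains RAS and MYC, had 9 of 18 members with intervals below equal levels and 1 above, with a median of -0.11 at percentile 4.62. let-7c-5p carried its largest ratio in size (2508 and 1586 CPM, log2 -0.66, interval -0.74 to -0.58), and let-7a-5p had a log2 ratio of 0.04. In the family of miR-34 and miR-449, miR-34a-5p was the member past the size rule, and the other 5 measured members had intervals that held equal levels. The family's median was 0.28 (counting interval -0.196 to 0.628) at percentile 96.8 (97.6 against unmatched lists).

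Among clusters expressed in placenta, no row analysed here belonged to the chromosome 19 cluster C19MC, a primate cluster expressed mainly in placental trophoblast. All reads outside the rows analysed came to about 643 (0.0246%) in the untreated and 83 (0.00787%) in the EGF library, which bounds what that cluster can have held if the authors' normalization counted it. The imprinted chromosome 14 cluster C14MC held 3.10% of counts without EGF and 3.26% with EGF. Its 65 measured members had a median log2 ratio of 0.063, at percentile 99.4, where random lists had a median of -0.050. The counting interval of the C14MC median, -0.019 to 0.103, held equal levels. That shift was small, with 7 intervals above equal levels, 3 below and 55 that held them. With no count minimum the C14MC percentile was 96.3. miR-127-3p was its most abundant member (log2 0.08, interval 0.05 to 0.11) and miR-539-5p had its largest ratio (log2 1.06, interval 0.17 to 2.04). Of the cluster that runs from miR-371 onwards on chromosome 19, miR-373-3p had 15 and 7 counts (log2 0.19, interval -1.32 to 1.59). Of the pluripotency-linked miR-302 cluster, miR-302b-3p had 11 and 11 counts (log2 1.21, interval -0.04 to 2.66).

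**Figure D3:**
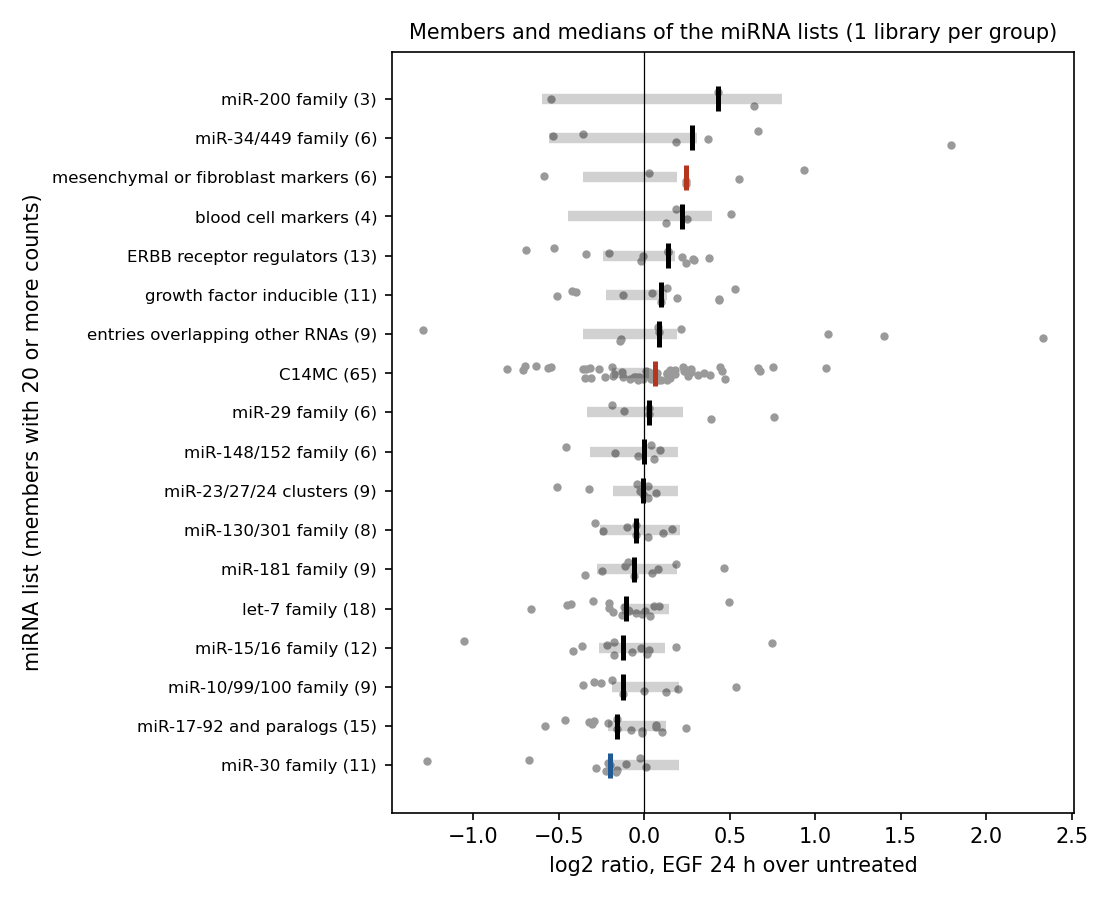
Log2 ratios of EGF over untreated for the members of the 18 lists with a percentile (points), the list median (vertical bar) and the central 95% of medians of 10000 matched random lists (grey band), 1 library per group. Red and blue bars lie outside the central 95%: C14MC and the mesenchymal markers above, the miR-30 family below.

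Proliferation-linked and other broad families lay inside the random range. The miR-17-92 cluster and its paralogs had a median of -0.16 (percentile 11.0), with 2 of 15 intervals above and 3 below equal levels. miR-92a-3p, its most abundant member, had a log2 ratio of -0.01 (interval -0.03 to 0.01), miR-19b-3p one of -0.58 (interval -0.87 to -0.30), and miR-92a-1-5p, with 39 and 14 counts, one of -0.16 (interval -1.16 to 0.75). The miR-15/16 family had a median of -0.12 (percentile 26.4), with miR-16-5p at -0.18 and miR-195-3p at -1.06, the latter with an interval of -3.60 to 0.60. In the miR-29 family, which represses collagens, miR-29a-3p (log2 0.39, interval 0.35 to 0.43) and miR-29b-3p (log2 0.76, interval 0.61 to 0.91) were higher, and the other 4 members had intervals that held equal levels (median 0.030, percentile 70.1). The miR-10/99/100 family had a median of -0.13 (percentile 16.3), with miR-100-3p at 0.53. The miR-23/27/24 clusters had a median of -0.005 (percentile 45.2), with miR-27b-3p at 0.02 (-0.002 with TMM scaling) and miR-27b-5p at -0.51. The miR-181 family had a median of -0.059 (percentile 35.5), with miR-181a-5p at -0.06 and miR-181a-3p at 0.47. The miR-130 and miR-301 family had a median of -0.048 (percentile 30.2), with miR-130a-3p at 0.02 (-0.003 with TMM scaling) and miR-301a-5p at -0.29. The miR-148 and miR-152 family had a median of 0.00 (percentile 57.4), whose sign differed between scalings. Its members miR-148b-3p and miR-152-5p stood at 0.06 and -0.46. Of the cluster of miR-183, miR-96 and miR-182, miR-182-5p had a log2 ratio of 0.27 (interval 0.13 to 0.40). Both arms of miR-210 were higher, with miR-210-3p at 0.36 (interval 0.22 to 0.50).

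Markers of other cell types were also read. The mesenchymal markers had a median of 0.24 over 6 members, at percentile 98.8, with 3 intervals above and 1 below equal levels. The 3 above were all miR-199 arms (miR-199a-3p, miR-199b-3p and miR-199a-5p). The 1 below was miR-143-3p (990 and 265 counts, log2 -0.59, interval -0.79 to -0.39), so these markers did not rise as a group. The list's most abundant member, miR-199b-3p (log2 0.24, interval 0.18 to 0.30), shares its reads with miR-199a-3p, and with such copies merged the percentile was 95.97. With no count minimum the median was 0.030 over 9 members, at percentile 91.3. miR-199b-5p had 11 and 9 counts (log2 0.93, interval -0.43 to 2.43). The epithelial miR-200 family had 74 and 35 counts in all (median 0.43, percentile 91.0, and 97.6 over 6 members with no count minimum), and miR-200c-3p had a log2 ratio of 0.64 (interval -0.56 to 1.86). The other epithelial markers had 9 and 3 counts. Endothelial miR-126-5p had a log2 ratio of 0.04 and miR-126-3p one of 0.05, both with intervals that held equal levels. The blood cell markers had a median of 0.22 (percentile 88.5), with miR-486-5p at 0.13 and miR-142-3p at 0.51, and no interval excluded equal levels. In the list of liver, muscle and neuroendocrine markers, both arms of the neural miR-9 were higher, miR-9-5p by a log2 ratio of 0.60 (628 and 952 CPM, interval 0.48 to 0.71) and miR-9-3p by 1.12 (interval 0.33 to 1.97). The 9 measured entries that overlap other RNAs had 3 intervals above and 3 below equal levels and a median of 0.087 (percentile 88.7). miR-1260b, the most abundant of them, had a log2 ratio of -0.14 (interval -0.21 to -0.07). Of the 18 lists, 3 lay outside the central 95% of matched random lists, and simulated lists with no effect did so in 7.5% of cases. The simulated lists had independent members and made-up levels, while the real lists hold partner arms and copies. That share is therefore not a calibrated rate for the real lists.

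The authors' deposited table of differential miRNAs named 56 miRNAs as higher and 80 as lower in EGF. Its title gives P of 0.05 and a fold change of 2 as thresholds, but the list held every miRNA with a deposited P of 0.05 or less whatever its fold, and 23 of them reached 2-fold in the authors' deposited table (12 higher, 11 lower). In the authors' deposited table, 48 of these miRNAs differed by less than 1.2-fold. Of the 22 miRNAs past the size rule, 20 were in the deposited list, each at 2-fold or more there. For 13 of the 35 miRNAs with at least 20 counts and a 2-fold ratio, the counting interval held equal levels.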

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

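The thinning of the untreated library was chosen after seeing the data. All 22 miRNAs past the size rule kept their direction under every alternative run, which was largely fixed in advance. The thresholds, count minimums and unmatched lists leave each ratio unchanged, and added reads shrink a ratio without reversing it. The scalings shift these ratios by far less than the 2-fold that the rule requires. All runs reuse the same 2 libraries. Signs differed for values near 0: miR-130a-3p and miR-27b-3p under TMM, the miR-148 and miR-152 family, and the ERBB regulators with no count minimum. Scaling by TMM, DESeq2 factors, totals without the 10 most abundant miRNAs or the deposited per-million values gave between 22 and 23 miRNAs past the size rule, of which at least 21 were among the 22 reported, and the median of miRNAs with at least 100 counts moved by less than 0.1 (log2). Adding 5 reads in place of 1 left 18, without miR-2682-5p, miR-9-3p, miR-539-5p and miR-33a-3p. A minimum of 100 counts left 10 (8 higher, 2 lower), since fewer miRNAs were considered, and put 5 lists outside the central 95% of random lists. These were C14MC, the miR-30 family, the mesenchymal markers, the ERBB regulators and the entries that overlap other RNAs (percentile 100 over 6 members); for the last the cause was not tested. A 1.5-fold threshold gave 41 (23 higher, 18 lower) and a 4-fold threshold 6 (3 higher, 3 lower), by construction. Without the entries that overlap other RNAs, the 5 most abundant miRNAs held 41.1% of counts in the untreated library and 42.2% in the EGF library, from the smaller total. The deposited list rebuilt with both stated thresholds held 23 miRNAs in place of 56 higher and 80 lower, since it drops smaller folds. With the untreated library thinned to the EGF total, a median of 11 were higher and 7 lower over 100 draws (ranges 7 to 16 and 3 to 10).

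Among values of single miRNAs and list medians, 616 stayed within their counting interval and 15 moved out of it, of which 9 did so under TMM scaling, which shifts abundant miRNAs with narrow intervals. The percentile of the mesenchymal markers was 91.3 with no count minimum, 95.97 with copies merged and 96.1 against unmatched lists. Depth limits the rarer miRNAs most: 434 miRNAs had at least 10 counts in the EGF library, against 562 in the untreated one. No paired analysis was possible because each group held 1 library.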

Other observations

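Tests of counting error, depth, GC content below 70% and the whole list of entries that overlap other RNAs were chosen after their results were seen, as were the correlations without hairpins far out on both axes and the counts of arms in one direction. The miR-33 family, which lies in introns of the sterol regulators SREBF2 (miR-33a) and SREBF1 (miR-33b), had log2 ratios above 0 on all 4 arms. miR-33a-5p had 66 and 46 counts (log2 0.78, interval 0.21 to 1.35), miR-33a-3p 19 and 16 (log2 1.01, interval 0.01 to 2.10), miR-33b-5p 39 and 26 (log2 0.71, interval -0.05 to 1.48) and miR-33b-3p 53 and 40 (log2 0.89, interval 0.28 to 1.52). These miRNAs were picked because of their values, and no explanation was tested. miR-34a-3p, the partner of miR-34a-5p, had 8 and 9 counts (log2 1.33, interval -0.07 to 3.06). The arms of miR-335 stood apart, with miR-335-3p at 0.74 (interval 0.44 to 1.05) and miR-335-5p at -0.24 (interval -0.66 to 0.17).

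Of the 14 miRNAs higher past the size rule, 8 had hairpins of at least 70% GC (8 of 32 such miRNAs against 6 of 473 with lower GC). At the real library sizes, 100 simulated pairs with no change gave at most 5 miRNAs higher. This argues against counting error of independent reads as the whole source, but the simulation holds no added spread from PCR or library preparation. Thinning left a median of 11. It keeps the EGF counts and the expected ratios, so it shows lost detection only and cannot decide on depth. All 14 kept a log2 ratio of 1 after a GC trend fitted on the other miRNAs was subtracted, but that trend leaves out the miRNAs in question. A second trend, over every miRNA with at least 100 counts, left 8. Its fit includes those of the 14 with that many counts, so it can remove part of their own rise. The prediction set beforehand named only the first trend. Of the risen miRNAs with high GC, the second trend left miR-4792 at 2.48 of 2.80 (log2), so it accounts for little of that rise. However, miR-3960 fell from 2.18 to 1.26, miR-6087 from 1.40 to 1.00 and the other 5 below 2-fold. For these 7, GC bias and a response to EGF cannot be told apart, although all 32 miRNAs of high GC had a median of only 0.24. For the other 6 (miR-34a-5p, miR-4454, miR-1246, miR-9-3p, miR-539-5p and miR-33a-3p) the second trend had a median of -0.056 (log2). This argues against hairpin GC as the source of their rise as a set. The trend was positive for miR-539-5p, which the correction moved from 1.06 to 0.96, below 2-fold. GC was that of the whole hairpin, so GC of the mature reads was not tested and stays open. Fragments of other RNAs may also contribute. The fixed list lay at percentile 88.7 with members moving both ways (percentile 100 over the 6 members with at least 100 counts, 95.5 over 15 with no count minimum). Of the 14 hairpins, 1 (miR-1246, 7.1%) shared 16 nt with another annotated non-coding transcript. Among the 491 other miRNAs with at least 20 counts, 25 did (5.1%), so this count tells little. The annotation lacks nuclear tRNAs and the 45S rRNA, so a part played by fragments stays open.

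The 153 intervals that exclude equal levels exceed the counting error of independent reads, but with 1 library per group they may reflect library preparation as well as EGF. If whole hairpins changed, both arms should move together, and across 97 hairpins with at least 50 counts on each arm the log2 ratios correlated with Pearson r = 0.29 and Spearman rho = 0.23 (percentile 99.8 of r among 10000 random re-pairings). miR-423 and miR-3184 both count among the 97, although miR-423-5p and miR-3184-3p appear to hold the same reads. After the GC trend was subtracted r was 0.27, as it was without the 2 hairpins farthest on the 5p axis (miR-210 and miR-1908), and 61 of the 97 hairpins had both arms in one direction, which 0.93% of re-pairings reached. Without the 2 hairpins farthest on both axes (miR-210 and miR-9) r was 0.22 (percentile 98.3), but without the 5 farthest, which add miR-33b, miR-625 and miR-1908, it was 0.10 (percentile 83.3) with 56 of 92 in one direction (2.99% of re-pairings). The size of r thus depends on a few hairpins, and a change of whole hairpins stays open. After the same subtraction, 82.4% of the 153 kept an interval that excludes equal levels, so GC content stays open as a part of the difference, as does any difference between the 2 cultures other than EGF.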
